A study of Homo sapiens with 4 samples.

How the data were processed

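Single-nucleus chromatin accessibility was measured in 4 libraries of Panc1 cells from transplanted mice, 2 given carrier and 2 given inflachromene. Groups were taken from the sample titles, which read Control and ICM and are called Carrier and Inflachromene here. Libraries are named by group and mouse number. Nuclei were isolated and libraries prepared with 10x Chromium single-cell ATAC reagents, per the labels' protocols. The submitters' processing notes name Cell Ranger ATAC 2.1.0, Cell Ranger ARC and the build GRCh38; the settings used and the role of each tool are not given in the sources used here. For each library the authors deposited a list of peaks and a matrix of whole-number counts per peak and barcode, with no normalization. The peak lists differ between libraries. Between 82.4% and 84.9% of the matrix entries above 0 are even, as happens where both ends of a fragment are counted. Thus 2 counts are often 1 molecule. Intervals of cluster shares are built on numbers of barcodes, so this does not narrow them. Peak positions were used as the files give them and written from 1. Lists of barcodes were not used.

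Peaks on chromosomes 1 to 22 and X that overlapped by at least 1 bp were merged over libraries, and a merged region with a peak in all 4 was kept as a consensus region (50771 of 128195, median width 936 bp). A library's count in a region is the sum over its own peaks there. A region without a peak in a library has no count rather than 0, so regions gained or lost outright are outside the tests and appear only as counts of peaks. Sums over peaks called separately move with how much was called: the peaks covered 67.2, 64.9, 67.0 and 82.4 Mb in Carrier 12, Carrier 31, Inflachromene 11 and Inflachromene 35.

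Promoters had been planned as the unit for genes. The gene table used, RefSeq's for the same build, gives the start and end of each gene without its strand, so start sites could not be told from gene ends. Regions within 1000 bp of either outer end of a protein-coding gene were used instead and are called gene ends. Where both ends had regions (1688 genes), the end with the higher mean over all libraries was taken; 11119 genes had a region at a single end, and 3602 genes share a region with another gene, so that their values are the same measurement. No genome sequence was used, so motif classes and GC content, both planned, were not analysed here.

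Counts were summed over all deposited barcodes of a library, since barcodes are not replicates and the mouse is. Differences between Inflachromene and Carrier were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr, which removed no consensus region and no gene end, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors lay between 0.975 and 1.03 for regions. Standard errors and intervals of log2 fold changes come from the quasi-likelihood statistic. The 20 gene lists, the markers of cell types and the tests of regions, gene ends, lists, the share of counts at gene ends and cluster shares were fixed before the data were examined; the tests of explanations, the windows of 10 Mb as a comparison and Fisher's exact test for the presence of a region were added later. Lists were tested on log2 CPM of gene ends with camera and fry of limma 3.58.1, and with Fisher's exact test for the presence of a region. DESeq2 1.42.0 was the other tool for single regions and gene ends.

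Named gene ends follow a rule fixed at the same time: HMGB1 and HMGB2 always, then up to 10 in each direction among those whose groups do not overlap. Of these, those past the threshold were taken by largest fold change, filled up by the smallest unadjusted p where fewer pass. From each list up to 4 members with the smallest unadjusted p may be named, and 4 regions away from gene ends in each direction by the same rule. A few items that the rule names are not reported here; counts and medians over groups include them.

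Barcodes were clustered on consensus regions with latent semantic indexing (term frequency and inverse document frequency, 30 components from scikit-learn 1.9.0) in Python 3.11.15. Component 1, whose correlation with log10 counts was 0.976, was left out. A graph of 15 nearest neighbours was divided by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 0.5. Clusters were to be named only from preset markers of carcinoma, fibroblast, endothelial, myeloid, T and NK, B, acinar, endocrine and Schwann cells. Rebuilt clusters were matched to these clusters by where most of their barcodes fell. No doublet caller was run; removal of barcodes of very high counts is among the alternatives. Shares were compared with two-sided exact permutation tests in scipy 1.17.1, and their 95% intervals are exact Clopper-Pearson intervals. Windows of 10 Mb with at least 20 consensus regions were summed over deep barcodes.

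The 95% interval of the log2 fold change lay wholly between -1 and 1 for 98.1% of gene ends and 88.3% of regions. The scripts were tested on simulated data drawn from the real means and library sizes. Their dispersion, the variation beyond counting error, followed the fitted trend over mean counts. Variation of single gene ends or regions around that trend was left out, so recovery in the real data may be lower. At gene ends, 74% of simulated changes of 1.5-fold and 98% of 2-fold were recovered with 50 changed gene ends per size. Among regions the shares were 4% and 52%, and 90% at 3-fold. False calls were 16 of 202 calls at gene ends and 5 of 128 among regions. A simulated shift of 0.2 on the log2 scale in the G1/S list was called by camera with the preset correlation (adjusted p = 5.10e-09) but not with an estimated correlation (unadjusted p = 0.0333, adjusted p = 0.666), nor was a shift of 0.4 with the latter (adjusted p = 0.110).

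Other settings, also fixed in advance, were median-of-ratios size factors, total counts without TMM, no low-count filter, leaving out each library in turn, only deep barcodes, removal of barcodes above 3 times the library median, regions covered by peaks to at least 0.5 of their length, an offset for 10 Mb windows, DESeq2, counting barcodes in place of counts, a window of 500 bp, all regions over the gene body, an estimated correlation, each library's own peaks, Leiden resolutions of 0.25 and 1.0, and thinning to 2000 counts. Where a library was left out, the lone library of its group was assumed to vary like the others. Chosen after seeing the data were removal of barcodes above 3 times the median of deep barcodes, only clusters 1 and 2, all but clusters 4 and 6, removal of cluster 5, as many random barcodes, cyclic loess offsets, both ends of a gene summed, only genes with a region at a single end, clustering without chromosomes 3, 9 and 12, and leaving out each library for the windows.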

Results

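Chromatin accessibility was measured in single nuclei of Panc1, a human pancreatic ductal adenocarcinoma cell line, from transplanted mice that had received carrier alone or inflachromene. Inflachromene is a small molecule known to bind the chromatin proteins HMGB1 and HMGB2. The design compared 2 Carrier libraries (mice 12 and 31) with 2 Inflachromene libraries (mice 11 and 35), and each library came from 1 mouse. Single-cell ATAC-seq marks open chromatin by the insertion of a transposase, and the deposited matrices give counts per peak and barcode. The libraries held 33336531 counts in 5186 barcodes (Carrier 12), 29295799 in 2039 (Carrier 31), 27088391 in 4067 (Inflachromene 11) and 39947056 in 3276 (Inflachromene 35). Barcodes with at least 2000 counts, called deep barcodes from here on, numbered 2070, 939, 1531 and 2060 in the same order. The remaining barcodes carried between 1.74% and 4.37% of a library's counts.

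The first question was which parts of the genome were open in these grafts. Peaks of the 4 libraries merged into 128195 regions, of which 50771 held a peak in every library. These consensus regions took 83.1% to 89.8% of each library's counts. Of 19974 protein-coding genes, 12807 (64.1%) had a consensus region within 1 kb of an outer end of the gene. All 24 genes of the G2/M and mitosis list had such a region, as did 24 of 25 genes of G1/S and DNA replication and all 19 genes of MYC targets and ribosome biogenesis. So did all 15 housekeeping controls and all 14 genes of TGF-beta and BMP response, so this was not particular to proliferation lists. In contrast, 3 of 19 genes of the classical pancreatic cancer subtype had a region (FOXA3, VSIG2 and GATA6), and 4 of 17 of the basal-like subtype (KRT15, AREG, S100A2 and LEMD1). Two-sided Fisher's exact tests against all protein-coding genes, adjusted over the 20 lists, gave p = 0.000415 for G2/M and mitosis and for the classical subtype, and p = 0.00431 for the basal-like subtype. For the housekeeping controls the same test gave an adjusted p of 0.00540. No library had a peak over the tumour suppressor gene CDKN2A (chromosome 9, 21967752 to 21995324, GRCh38) or over CDKN2B (22002903 to 22009313). The nearest consensus regions ended at 21814388 and began at 22373503. A lack of peaks cannot tell closed chromatin from missing DNA, and DNA copy number was not analysed here.

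Peak lists overlapped to a similar degree within and between the groups. The share of merged regions common to a pair of libraries was 62.6% for the Carrier pair and 57.2% for the Inflachromene pair, and between 58.0% and 60.5% across groups. Both Inflachromene libraries and neither Carrier library had a peak in 4666 regions, and the reverse held for 2046. Pairs made of 1 library of each group had between 1670 and 4414 such regions. The largest of these counts involved Inflachromene 35, the library with the most counts.

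HMGB1 and HMGB2, the known binding partners of the compound, were examined first. Accessibility at the HMGB1 gene end (chromosome 13, 30617237 to 30618136, a region shared with USPL1) was 122 ± 4.44 CPM (counts scaled to a common total of gene-end counts; SD, n = 2) under Carrier and 118 ± 3.80 (SD, n = 2) under Inflachromene. Its log2 fold change was -0.05 (standard error 0.07, 95% interval -0.22 to 0.11), and edgeR gave an adjusted p of 0.975. Only outer ends of genes were used, so a start site inside HMGB1 was not measured. The region is also an end of USPL1, so these values cannot be assigned to HMGB1 alone. At the HMGB2 gene end (chromosome 4, 173334179 to 173335022) the levels were 103 ± 9.80 and 107 ± 8.42 CPM (SD, n = 2 each), with a log2 fold change of 0.05 (standard error 0.09, 95% interval -0.16 to 0.26, edgeR adjusted p = 0.988). The HMGB2 level was 110 and 113 CPM in Carrier 31 and Inflachromene 11, where a cluster of mostly shallow barcodes, cluster 4, held 9.42% and 9.71% of barcodes. It was 96.2 and 101 CPM in Carrier 12 and Inflachromene 35, where that cluster held 5.40% and 5.62%. Of deep barcodes, cluster 4 held 10.2% in Carrier 31, 2.02% in Inflachromene 11, 0.0% in Carrier 12 and 0.340% in Inflachromene 35. The HMGB2 log2 fold change was -0.02 among deep barcodes, 0.09 in clusters 1 and 2, 0.04 without clusters 4 and 6 and 0.02 with the offset for 10 Mb windows. This fold change was -0.04 without Carrier 12 and -0.03 without Inflachromene 11, and 0.15 and 0.13 without Carrier 31 and Inflachromene 35. That of HMGB1 was 0.04 when barcodes were counted in place of counts, -0.03 in clusters 1 and 2, -0.09 without Carrier 12 and without Inflachromene 11, and -0.02 without Carrier 31 and without Inflachromene 35. Removal of barcodes above 3 times the library median gave -0.55 for HMGB2 and -0.19 for HMGB1, but it kept 2997, 1262 and 2602 mostly shallow barcodes in Carrier 12, Carrier 31 and Inflachromene 11 and 3263 of 3276 in Inflachromene 35, so these values compare barcodes of unlike depth.

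No gene end passed the edgeR test between Inflachromene and Carrier. Among gene ends higher under Inflachromene whose groups did not overlap, the 10 with the smallest unadjusted p did not pass. They lay at 6 separate regions. TPRG1 (chromosome 3, 189324459 to 189325441) had the largest log2 fold change, 1.94 (standard error 0.31), with 18.3 and 36.3 CPM in the Inflachromene libraries against 7.13 and 7.15 in the Carrier libraries. TRIM6, which shares its region with the TRIM6-TRIM34 readthrough gene on chromosome 11, stood at 0.90 (standard error 0.15), and PCID2 with CUL4A, a scaffold of ubiquitin ligases, at 0.53 (0.09). The region shared by ASPRV1 and PCBP1 stood at 0.45 (0.08) and that of FAM76B and CEP57 at 0.41 (0.07).

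Among gene ends lower under Inflachromene whose groups did not overlap, the 10 with the smallest unadjusted p did not pass either. Many were neighbours in the genome. On chromosome 9, between 19048859 and 21803038, lay SAXO1 with RRAGA (-0.41, standard error 0.09), HAUS6 (-0.40, 0.08), the lipid droplet gene PLIN2 (-0.51, 0.10) and MTAP, which encodes methylthioadenosine phosphorylase (-0.39, 0.08). On chromosome 12, between 25958107 and 26126855, lay RASSF8 (-0.38, 0.06), SSPN (-0.47, 0.07) and BHLHE41 (-0.48, 0.09). The remaining members were SEMA5A on chromosome 5 (-0.66, 0.11) and S100A6 on chromosome 1 (-0.41, 0.08). All 20 gene ends had both Inflachromene libraries on the same side of both Carrier libraries, since the naming rule kept only such gene ends.

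Of 12807 gene ends, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, with 732 (5.72%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.265. DESeq2 called 23 gene ends, 14 higher and 9 lower, several of which share a region with another. Among them were all gene ends named above as higher or lower except S100A6, so whether these pass depends on the tool. Groups did not overlap at 34.5% of gene ends, where chance gives 33.3%. Leaving out Inflachromene 11 gave 76 called gene ends (54 higher, 22 lower), and leaving out Inflachromene 35 gave 7, all lower. Among barcodes of clusters 1 and 2, the main clusters of deep barcodes in Carrier libraries, the log2 fold changes of HAUS6 (0.05) and SAXO1 with RRAGA (0.05) had the opposite sign.

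**Figure D1:**
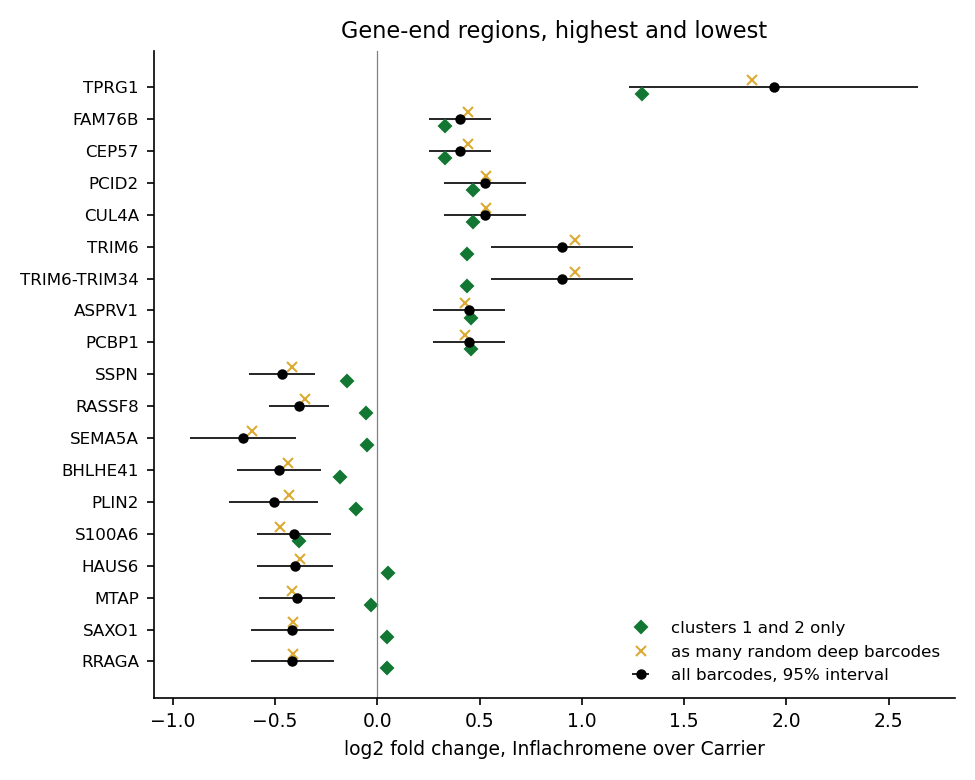
Log2 fold change of accessibility (horizontal axis, Inflachromene over Carrier, 2 libraries each) at the gene ends named as higher and the 10 named as lower; black points and bars give the edgeR estimate over all barcodes with its 95% interval, green diamonds the estimate in clusters 1 and 2, and yellow crosses that in as many random deep barcodes. PLIN2 stands at -0.51 over all barcodes and at -0.11 in clusters 1 and 2; TPRG1 stands at 1.94 and 1.29; no gene end passed the edgeR test in either set.

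Away from gene ends, the regions with the smallest unadjusted p among those whose groups did not overlap did not pass either. Higher under Inflachromene were a region within PRKCE, which encodes protein kinase C epsilon (chromosome 2, 45991924 to 45992876, log2 fold change 2.15, standard error 0.35), and a region 2065 bp from the chemokine gene CCL2 (chromosome 17, 34252173 to 34253220, 1.54, 0.26). A region within EFHB (chromosome 3, 19888886 to 19889830) stood at 0.98 (0.17) and a region on chromosome 3 (30258606 to 30259663) whose nearest gene is RBMS3 at 1.45 (0.25). Lower were a region within EGF, the epidermal growth factor gene (chromosome 4, 109921088 to 109922044, -1.19, 0.26), a region within ANO7 (chromosome 2, 241207152 to 241208911, -1.06, 0.25), and regions nearest to CTSO (chromosome 4, 156293527 to 156295179, -1.41, 0.29) and LOC107987004 (chromosome 9, 63335046 to 63335988, -1.29, 0.30). All had n = 2 libraries per group.

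Of the 50771 consensus regions, edgeR called 0 at an adjusted p under 0.05, with 2274 (4.48%) at an unadjusted p under 0.05. DESeq2 called 28 regions, all higher under Inflachromene, among 42896 with an adjusted p; those near PRKCE, CCL2, EFHB and RBMS3 were among them. Leaving out a library changed this count: 3180 regions (2780 higher, 400 lower) without Inflachromene 11, 299 (159 higher, 140 lower) without Inflachromene 35, 5 without Carrier 31 and 0 without Carrier 12. Those called without Carrier 31 included regions nearest to LOC102724250, HS3ST1, ERGIC1 and BARX1, which were singled out after their values were seen.

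Gene lists fixed in advance were compared next, since the title of the series names pro-proliferative programs. Proliferation lists showed small values in both directions. Of 24 measured members of G1/S and DNA replication, 16 had a value above 0 and the mean log2 fold change was 0.03; RRM1, a ribonucleotide reductase subunit, stood at 0.29 (standard error 0.09), POLE at 0.26 (0.09), MCM7 at -0.17 (0.07) and CDC45 at -0.15 (0.07). G2/M and mitosis had 10 of 24 members above 0 and a mean of -0.01, with MKI67 at 0.15 (0.08) and BIRC5 at -0.17 (0.09). MYC targets and ribosome biogenesis had 13 of 19 above 0 and a mean of 0.04, with ODC1 at 0.21 (0.10) and CAD at 0.26 (0.13). Of the 9 measured architectural chromatin proteins, 7 had a value below 0 and the mean was -0.06, with HMGN4 at -0.27 (0.10) and HMGN2 at -0.15 (0.08). The housekeeping controls had 7 of 15 above 0, a median of -0.00 and a mean of 0.00, with PGAM1 at 0.21 (0.08) and ACTB at -0.10 (0.07).

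No signalling list passed the test. TGF-beta and BMP response had 9 of 14 members above 0 and a mean of 0.13; adjusted over the list alone, 2 members passed, ID3 at 0.58 (standard error 0.11) and BHLHE40 at 0.45 (0.12), and 0 passed over all gene ends. ID2 stood at 0.40 (0.15) and TGFBR2 at 0.33 (0.14). BHLHE40 and TGFBR2 on chromosome 3 and ID2 on chromosome 2 lay in 10 Mb windows whose counts as a whole were higher under Inflachromene, with log2 differences of 0.32, 0.14 and 0.19. That of the BHLHE40 window was 0.19 without Carrier 12, and that of the TGFBR2 window 0.08 without Carrier 12 and without Inflachromene 35. NRF2 targets had 4 of 12 members above 0, a median of -0.01 and a mean of 0.09; adjusted over the list alone, 2 passed, ME1 at 0.93 (0.22), an NADPH-producing malic enzyme, and OSGIN1 at 0.60 (0.16). Immediate early and MAPK feedback genes had 16 of 21 above 0 (FOSL2 at 0.18, 0.08; JUND at 0.16, 0.08), and p53 targets and cell cycle arrest 11 of 14 (PHLDA3 at 0.38, 0.15; CDKN1B at 0.17, 0.10). Interferon response and antigen presentation had 12 of 19 above 0 (IRF1 at 0.24, 0.07; IFIT3 at 0.43, 0.19), and NF-kB targets and secreted inflammatory factors 9 of 15 (NFKBIA at 0.19, 0.09; CXCL8 at 0.45, 0.27).

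Lists of cell identity, stress and metabolism did not pass either. Mesenchymal genes had 11 of 16 members below 0 and a mean of -0.08, with LOX, a collagen cross-linking enzyme, at -0.36 (standard error 0.10), TNC at -0.51 (0.17) and ITGA5 at 0.31 (0.13). Epithelial genes had 5 of 9 below 0 (CDH1 at -0.33, 0.27; CLDN4 at 0.35, 0.29). The classical subtype had 2 of 3 measured members below 0 (GATA6 at -0.08, 0.20) and the basal-like subtype 1 of 4 (KRT15 at -0.46, 0.26). YAP and TEAD targets had 8 of 12 above 0 (YAP1 at 0.22, 0.10; NUAK2 at -0.20, 0.12), hypoxia and glycolysis 11 of 16 (LDHA at 0.22, 0.08; BNIP3 at 0.12, 0.08), and apoptosis regulators 8 of 12 (BMF at -0.08, 0.08; BCL2L1 at 0.07, 0.07). The unfolded protein and amino acid response had 8 of 13 below 0 (TRIB3 at -0.28, 0.12; ASNS at -0.35, 0.18), and sterol synthesis 7 of 11 above 0 (INSIG1 at -0.14, 0.07; DHCR7 at 0.12, 0.09).

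limma camera with a preset correlation of 0.01 called 0 of the 20 lists. The smallest adjusted p was 0.280, for TGF-beta and BMP response (unadjusted 0.0269) and for immediate early genes (unadjusted 0.0280). With an estimated correlation the smallest unadjusted p of any list was 0.143 and the smallest adjusted p 0.917. That version did not call a simulated shift of 0.4 in the G1/S list, so its lack of calls cannot decide whether a list moved. Fry, which asks whether a list's genes move one way on balance, gave an adjusted p of 0.129 for TGF-beta and BMP response, its smallest. Summing all regions over the gene body gave a call for that list (camera adjusted p = 0.0428, in a range of 0.0428 to 0.979 over all settings; unadjusted p = 0.137 with an estimated correlation). Without Carrier 31 camera called immediate early genes as higher (unadjusted p = 0.202 with an estimated correlation). Without Inflachromene 11 it called NF-kB targets, interferon response and the basal-like subtype as higher (0.137, 0.171 and 0.180 with an estimated correlation), and without Inflachromene 35 epithelial genes and the basal-like subtype as lower (0.490 and 0.208). The direction camera gave for signalling lists, higher for all 6 over all barcodes, turned for some in other settings. Without Inflachromene 35 it was lower for NF-kB targets (camera unadjusted p = 0.0240) and interferon response (0.376). In clusters 1 and 2 it was lower for p53, NF-kB and NRF2 targets and interferon response, and TGF-beta and BMP response had a camera unadjusted p of 0.979. Immediate early genes and MYC targets were called there as higher (camera adjusted p = 0.0322 and 0.0364; unadjusted p = 0.150 and 0.196 with an estimated correlation).

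**Figure D2:**
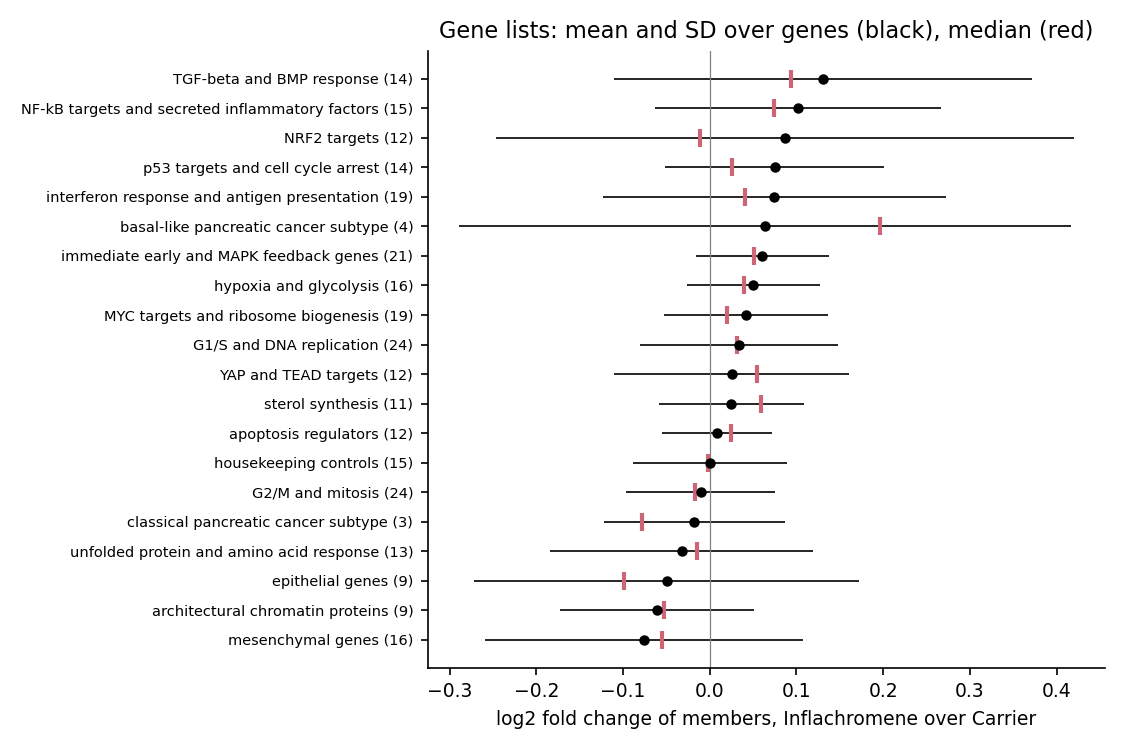
Log2 fold change of accessibility at gene ends (horizontal axis, Inflachromene over Carrier, 2 libraries each) for the 20 gene lists, with the number of measured members in brackets; black points and bars are the mean and SD over genes, which are not replicates, and red ticks the median. Means run from -0.08 for mesenchymal genes to 0.13 for TGF-beta and BMP response, and no list passed camera.

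The share of counts that fell at gene ends was compared as a measure of where in the genome open chromatin lay. It was 49.4% in Carrier 12, 52.5% in Carrier 31, 53.6% in Inflachromene 11 and 48.9% in Inflachromene 35. The means were 51.0% ± 2.21 under Carrier and 51.3% ± 3.36 under Inflachromene (SD, n = 2 each), a difference of 0.316 percentage points that was smaller than either spread (two-sided exact permutation p = 1.0). With 2 libraries per group the smallest p this test can give is 0.333. The sign turned with each library's own peaks (-0.839), without Carrier 12 (-1.25) and without Inflachromene 11 (-2.06), and the difference was 1.88 without Carrier 31 and 2.69 without Inflachromene 35.

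Barcodes were then clustered to ask whether the groups differed in the makeup of accessibility states. Cluster 3 was the state whose share lay furthest towards Inflachromene in both libraries. It held 9.95% of deep barcodes in Carrier 12 (95% exact Clopper-Pearson interval 8.70 to 11.3) and 8.20% in Carrier 31 (6.53 to 10.1), against 30.2% in Inflachromene 11 (27.9 to 32.6) and 27.3% in Inflachromene 35 (25.4 to 29.3). The means were 9.08% ± 1.24 and 28.8% ± 2.06 (SD, n = 2 each), a difference of 19.7 percentage points that was larger than the spread within either group. Cluster 5 made up 23.3% of deep barcodes in Inflachromene 35 (21.4 to 25.1), 1.76% in Inflachromene 11, 0.0966% in Carrier 12 and 0.319% in Carrier 31. Cluster 1 took 47.6% and 29.4% of deep barcodes in Carrier 12 and Carrier 31, and 12.4% and 22.7% in Inflachromene 11 and Inflachromene 35. The intervals cover counting error only.

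The two-sided exact permutation test gave p = 0.333 for each of these 3 clusters, the smallest value that 2 against 2 libraries allow, so that no share can pass a threshold of 0.05. Over all barcodes, cluster 3 held 4.72% ± 0.126 under Carrier and 15.3% ± 3.31 under Inflachromene (SD, n = 2 each). With every barcode thinned to 2000 counts its shares were 9.25% and 11.6% in Carrier 12 and 31, and 26.3% and 30.4% in Inflachromene 11 and 35. The thinned set left out 3131, 1126, 2583 and 1255 barcodes in the same order, those with under 2000 counts in consensus regions. With clusters rebuilt without chromosomes 3, 9 and 12, a setting added after seeing the data, cluster 3 held 9.23%, 5.01%, 27.0% and 26.6% of deep barcodes in the same order.

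**Figure D3:**
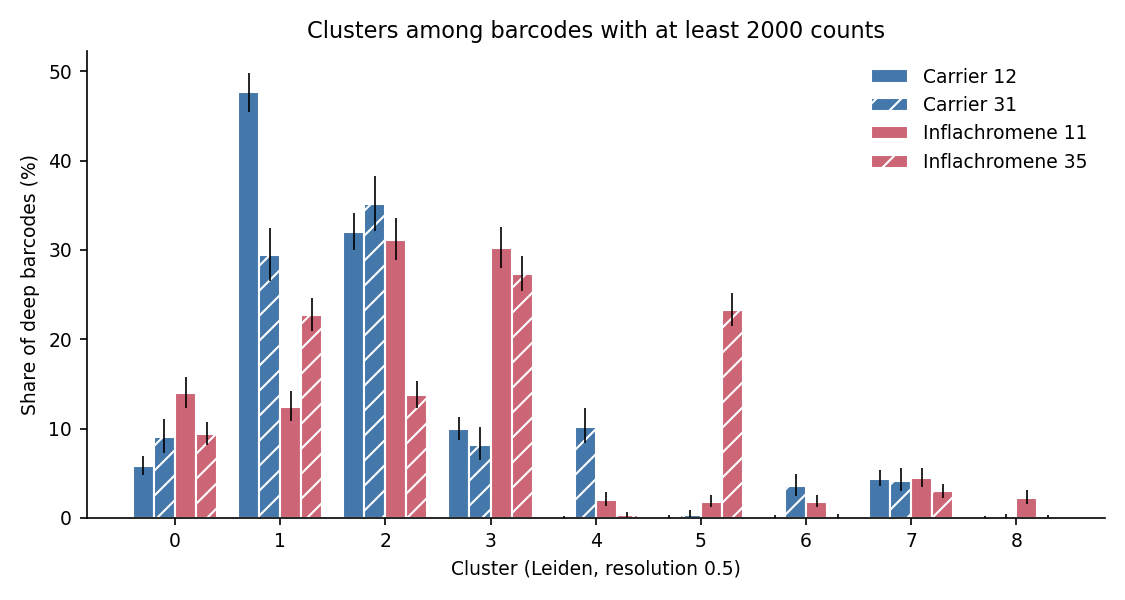
Share of deep barcodes (vertical axis, percent) in each of the 9 clusters for the 4 libraries; error bars are 95% exact Clopper-Pearson intervals, which cover counting error only. Cluster 3 holds 9.95% and 8.20% in the Carrier libraries and 30.2% and 27.3% in the Inflachromene libraries, and cluster 5 holds 23.3% in Inflachromene 35.

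All 9 clusters kept their numbers, since no preset cell type marker stood among the 10 leading gene ends of any cluster. Relative to clusters 1 and 2 together, cluster 3 was set apart by higher accessibility at MGMT, ALCAM and TPRG1 and lower accessibility at SEMA5A, MLLT3 and PLIN2. PLIN2, SAXO1, RRAGA and HAUS6, all among the 10 lowest gene ends of cluster 3, lay at 10 to 20 Mb of chromosome 9. Counts of cluster 3 were lower there as a whole, with the lowest window of that chromosome at a log2 ratio of -0.80. Their lower values are thus not particular to single gene ends. Cluster 5 was set apart by higher PDE3A and TPRG1 and lower BCAT1, INHBA and HAS2. Several of these gene ends are also among those named for the comparison of groups. Clusters 4 and 6 were mostly shallow, with medians of 1194 and 951 counts per barcode, and cluster 0 was the shallowest large cluster, with 6623 barcodes and a median of 247.0. Over all barcodes, cluster 1 held 19.8% and 13.9% in Carrier 12 and 31 and 7.40% and 14.7% in Inflachromene 11 and 35, so that its groups overlapped. Clusters 0, 2 and 8 also had groups that did not overlap over all barcodes; the means under Carrier and Inflachromene were 50.1% and 39.8% for cluster 0, 15.6% and 11.5% for cluster 2, and 0.267% and 0.995% for cluster 8. Among deep barcodes the direction for cluster 0 was the opposite, with means of 7.42% ± 2.30 under Carrier and 11.7% ± 3.22 under Inflachromene (SD, n = 2 each), and the groups did not overlap either.

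In a comparison added after seeing the data, the counts of deep barcodes were also summed in 297 windows of 10 Mb, to see whether differences ran over long stretches of chromosomes. The windows named here were singled out after their values were seen. Relative to Carrier, Inflachromene libraries had lower counts at 10 to 30 Mb of chromosome 9 (log2 differences of -0.32 and -0.33) and at 20 to 30 Mb of chromosome 12 (-0.20). On chromosome 12 the log2 ratio to all deep barcodes was -0.26 in Inflachromene 11 and 0.03 in Inflachromene 35, against 0.11 and 0.05 in Carrier 12 and Carrier 31, so that the difference came mostly from Inflachromene 11. They had higher counts at 0 to 20 Mb of chromosome 3 (0.32 and 0.25). On chromosome 2 all 16 windows between 0 and 160 Mb were higher, by 0.13 to 0.22 (median 0.16), and the groups did not overlap in any of them. On chromosome 11 the values ran from -0.08 to 0.19 (median 0.11), with 13 of 14 windows above 0 and groups apart in 12. Windows lay below 0 in 9 of 9 cases on chromosome 17 (median -0.07, groups apart in 6) and 15 of 16 on chromosome 7 (median -0.07, groups apart in 11). Single libraries moved several of these differences. Without Carrier 12 they were 0.19 at 0 to 10 Mb and 0.16 at 10 to 20 Mb of chromosome 3, 0.10 at 0 to 10 Mb of chromosome 11 and -0.21 at 20 to 30 Mb of chromosome 9, and without Inflachromene 35 0.14 at 10 to 20 Mb of chromosome 3. At 30 to 40 Mb of chromosome 3 the difference, 0.14, was 0.08 without Carrier 12 and without Inflachromene 35. Without Carrier 12 it was also 0.08 at 20 to 30 Mb and at 70 to 80 Mb of chromosome 2 (0.15 each with all libraries). The median between 0 and 160 Mb of chromosome 2 was 0.11 without Carrier 12, and that of chromosome 7 was -0.04 without Inflachromene 35. On chromosome 12 the difference was -0.05 without Inflachromene 11 and -0.34 without Inflachromene 35. The named gene ends MTAP, PLIN2, HAUS6, SAXO1 and RRAGA lay in the windows on chromosome 9, RASSF8, SSPN and BHLHE41 in that on chromosome 12 and HMGN4 in a window of chromosome 6 at -0.14. In Inflachromene 11 and 35, RASSF8 stood at 284.7 and 274.5 CPM, SSPN at 144.8 and 141.3, and BHLHE41 at 182.2 and 185.8. These 3 were thus as low in Inflachromene 35, whose window ratio of 0.03 lay near the 0.05 of Carrier 31. Higher windows held BHLHE40 (0.32), TGFBR2 (0.14) and the regions at EFHB (0.25) and RBMS3 (0.14) on chromosome 3. On chromosome 2 they held ID2 (0.19), ODC1 (0.22), CAD and FOSL2 (0.15 for both), ASPRV1 with PCBP1 (0.15) and the region in PRKCE (0.19). On chromosome 11 they held TRIM6, RRM1 and LDHA (0.18 for each) and FAM76B with CEP57 (0.17). The root mean square difference over windows was 0.08 for the real grouping, against 0.05 and 0.06 for the other pairings of the 4 libraries. Groups did not overlap in 92 of the 297 windows, where chance gives 33.3%. The pairing of Carrier 12 with Inflachromene 35 set 128 windows apart and that of Carrier 12 with Inflachromene 11 77, and 3 pairings cannot give a p under 0.333 in an exact permutation test.

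**Figure D4:**
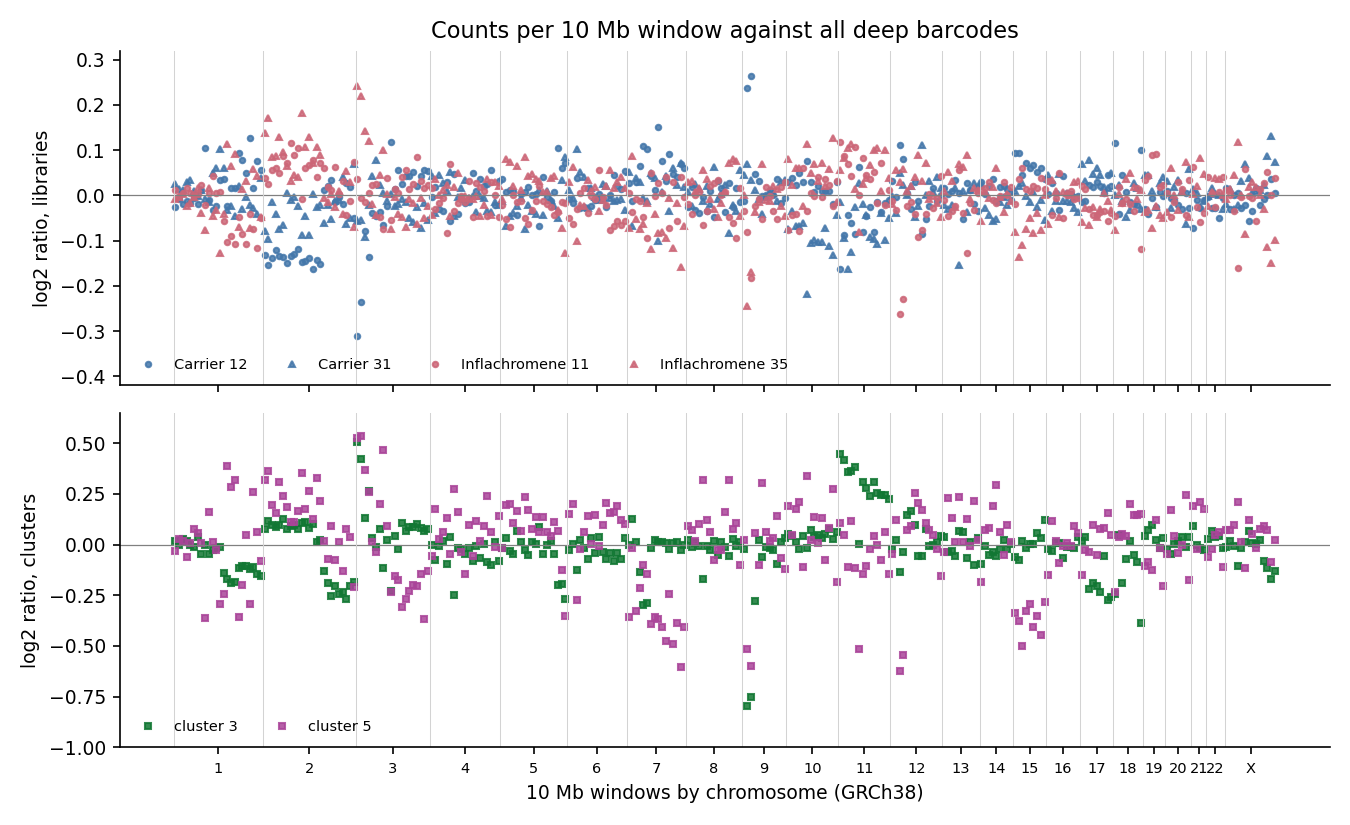
Log2 ratio of the share of counts in each 10 Mb window to that of all deep barcodes (vertical axes) along the chromosomes of GRCh38 (horizontal axis); the upper panel shows the 4 libraries and the lower panel clusters 3 and 5. Inflachromene libraries lie below Carrier libraries at 10 to 30 Mb of chromosome 9, where cluster 3 stands at -0.80 and -0.75. The lowest window of cluster 5 on chromosome 9 stands at -0.60.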

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

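The settings given here were fixed in advance, except those said to be added after seeing the data. The counts of called regions and gene ends stayed at 0 with other size factors, total counts, no filter, deep barcodes, regions covered to at least 0.5, the 10 Mb offset, barcodes in place of counts, a window of 500 bp for gene ends and, added after seeing the data, cyclic loess, clusters 1 and 2 alone, all but clusters 4 and 6, both ends summed and genes with a region at a single end. The smallest adjusted p for gene ends over those settings ran up to 1.000 and was 0.0955 with the 10 Mb offset. DESeq2 called 28 regions and 23 gene ends; the cause was not tested. Without single libraries the count of regions ran from 0 to 3180, that of gene ends from 0 to 76 and that of lists from 0 to 3, the highest each time without Inflachromene 11. Without Inflachromene 35 there were 299 regions, 7 gene ends and 2 lists (epithelial and basal-like, both lower). Without Carrier 31 there were 5 regions and 1 list (immediate early genes, higher). Without Inflachromene 11 the lists were NF-kB targets, interferon response and the basal-like subtype, all higher. Only clusters 1 and 2 called 2 lists (MYC targets and immediate early genes, both higher) and gene bodies 1 list, and the cause was not tested. No list was called with an estimated correlation. That version did not call a simulated shift of 0.4 in the G1/S list either, so its lack of calls cannot decide whether a list moved.

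Without Inflachromene 11, removing cluster 5 (an added test) left 1298 called regions and 5 gene ends, and removing as many random deep barcodes left 4275 and 196. The difference in the share of counts at gene ends, 0.316 points, turned to -0.839 with each library's own peaks and ran from -2.06 to 2.69 when libraries were left out; the cause was not tested. For cluster 3 the difference in share of all barcodes, 10.6 points, ran from 8.22 to 12.9 without single libraries and was 17.6 and 9.91 at resolutions 0.25 and 1.0 and 10.5 when clustered without chromosomes 3, 9 and 12 (added). Among deep barcodes it was 19.7, and 18.0 after thinning. Clusters 2 and 5 had no counterpart at resolution 0.25, cluster 2 none without chromosomes 3, 9 and 12, and clusters 0 and 8 none after thinning. At resolution 0.25 the cluster matched to cluster 3 held 31.8% of all barcodes in Inflachromene 35 and 12.7% in Inflachromene 11. At resolution 0.5 cluster 3 held 17.6% and 12.9% of them, and cluster 5 held 14.7% in Inflachromene 35. The difference of 17.6 points may thus take in cluster 5, and its rise came from Inflachromene 35. The difference of cluster 5, 7.54, was 0.602 without Inflachromene 35 and 14.5 without Inflachromene 11, that of cluster 0, -10.3 over all barcodes and 4.27 among deep barcodes, was -3.98 and -16.6 over all barcodes, that of cluster 2, -4.14, was -1.48 and -6.80, and that of cluster 8, 0.727, was 1.36 and 0.0991. Of 109 named values, 38 changed sign without being called in at least 1 setting, among them 5 of the 20 highest and lowest gene ends; 20 did so in clusters 1 and 2 alone. Removal of barcodes above 3 times the library median, left out of these counts, took most deep barcodes of 3 libraries and few of Inflachromene 35, so it says nothing about stability. The added version with the median of deep barcodes left all but 2 barcodes in place, so it tests nothing. No named value was called in the opposite direction. Motif classes and GC content were not run. No paired analysis was possible because the groups share no replicate numbers. In simulated data of this depth a 2-fold change at a gene end was mostly recovered and a 1.5-fold change of a single region mostly not. The simulation left out variation around the dispersion trend, so recovery in the real data may be lower.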

Other observations

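The tests of explanations given here were chosen after the result was seen, apart from the removal of cluster 5, which was set down before its count was known; its control with random barcodes was added afterwards. The test for host nuclei replaced one on the share of counts in the 1% of regions with the most counts (23.6% in cluster 4, 18.5% in cluster 6 and 7.03% in cluster 1) after gene ends at 0 had been seen. Clusters 4 and 6, which held 1051 and 435 barcodes, had a profile far from that of the other clusters. Levels per cluster are in CPM of all counts in consensus regions, so they lie below those of the report, which are scaled to gene-end counts. The gene ends of both clusters were led by BPIFB1, with 360 CPM in cluster 4 and 424 CPM in cluster 6 against 2.21 CPM in clusters 1 and 2, and cluster 4 also by IKZF1, a transcription factor gene of blood cells, with 353 CPM against 2.70 CPM. HMGB2 stood at 596 CPM in cluster 4 and 343 CPM in cluster 6, against 48.1 CPM in cluster 1. Of the preset markers, the 10 measured carcinoma genes had a median log2 ratio of -0.59 in cluster 4 and -0.86 in cluster 6 to clusters 1 and 2, the 5 measured myeloid genes -0.34 and -0.57, and the 5 measured fibroblast genes -0.99 and -2.28. The B cell and Schwann cell genes had medians above 0 in both clusters, with 2 measured members each, too few to name a cluster.

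Clusters 3 and 5 differed from the other deep barcodes over long stretches of chromosomes. In cluster 3 all 14 windows of chromosome 11 lay above 0, with a median log2 ratio of 0.29, and 7 of 9 windows of chromosome 17 lay below 0, with a median of -0.20. In cluster 5 all 16 windows of chromosome 7 lay below 0 (median -0.36), as did all 9 windows of chromosome 15 (median -0.35). The lowest window of chromosome 9 stood at -0.80 in cluster 3 and -0.60 in cluster 5. The highest of chromosome 3 stood at 0.51 and 0.54, so neither trait was particular to cluster 3. Within every library, the share of a barcode's counts at 10 to 30 Mb of chromosome 9 was lower in barcodes with a higher share at 0 to 30 Mb of chromosome 3, with Spearman correlations across barcodes, which are not replicates, of -0.16, -0.20, -0.45 and -0.55 in Carrier 12, Carrier 31, Inflachromene 11 and Inflachromene 35. Of 265 windows on other chromosomes, 22, 23, 2 and 1 had a correlation at least as negative in the same order. Each of these was a single window of 10 Mb, whose fewer counts draw a correlation towards 0. Its rank against the wider stretch of chromosome 3 is therefore not a like comparison.

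The higher share of cluster 3 in both Inflachromene libraries is the first pattern. Thinning argues against depth per barcode as the cause, since after thinning the difference was 18.0 percentage points against 19.7 among unthinned deep barcodes. An offset between whole libraries is also argued against: with clusters rebuilt without chromosomes 3, 9 and 12, cluster 3 had lower counts on chromosome 9 inside each library than the rebuilt cluster matched to cluster 1, whose deep barcodes came from clusters 1 (56.2%) and 2 (42.2%), and the log2 ratio nearest to 0 was -0.95 (95% bootstrap interval over barcodes -1.02 to -0.89). The hypothesis is that cluster 3 may be a subclone of Panc1 with other copy numbers, which a measurement of DNA copy number in the line and the grafts, not analysed here, would test. Whether treatment favoured it or the grafts differed by chance cannot be told apart with 2 mice per group, since the exact permutation p is 0.333.

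The second pattern is the set of differences at gene ends and regions between the groups. Different shares of clusters are a candidate explanation: over the 15 regions behind the 20 highest and lowest gene ends, the median log2 difference in the named direction was 0.47 over all barcodes, 0.15 in clusters 1 and 2, and 0.43 in as many random deep barcodes. Since the clusters were built from the same counts, the 8 regions on chromosomes 3, 9 and 12 were also read in that rebuilt cluster, made without these chromosomes, where their median was 0.03 against 0.44 over all barcodes. In clusters 1 and 2 TPRG1 stood at 1.29 (1.94 over all barcodes), PCID2 with CUL4A at 0.47 (0.53), ASPRV1 with PCBP1 at 0.46 (0.45), FAM76B with CEP57 at 0.33 (0.41) and S100A6 at -0.38 (-0.41), so part of the pattern stays open. Cluster 5 may account for part of the calls made without Inflachromene 11, since 3180 regions went to 1298 without its barcodes and to 4275 without random ones.

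The third pattern is the profile of clusters 4 and 6. Free DNA of the carcinoma is argued against, since the root mean square log2 ratio over 10 Mb windows was 0.68 in cluster 4 and 0.63 in cluster 6, but 0.04 in cluster 0, which was shallower. Nuclei of the mouse host, whose reads align to the human genome only where the sequences match, are a candidate source: 19.1% of 10334 gene ends with at least 20 expected counts held under 0.1 of them in cluster 4 and 7.85% of 5682 in cluster 6, against 0 of 12641 in cluster 0. No mouse genome was used here, so the alignment itself stays untested, and no biological explanation by treatment was tested. Leaving both clusters out changed no count of calls. These counts were already 0 with both clusters in place and could only have risen, so this does not show that the clusters had no influence.

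The other pairings of the 4 libraries, which mix the groups, gave at most 1 called region and 1 called gene end, against 0 and 0 for the real grouping. Carrier 12 with Inflachromene 35 against the rest gave 5984 regions at an unadjusted p under 0.05, against 2274 for the real grouping, and 788 gene ends against 732. These libraries also had the most counts (33336531 and 39947056) and the lower shares of cluster 4 (5.40% and 5.62%) and of counts at gene ends (49.4% and 48.9%); what sets this pairing apart was not tested. The 3 pairings are too few for a share under 0.05.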
